A study of Mus musculus with 16 samples.

How the data were processed

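Gene expression was measured in livers of 16 male mice on 16 one-colour Agilent arrays, 1 mouse per array. Per the labels, all 16 mice were homozygous for the floxed Cdh1 gene (fl/fl). Of these, 8 carried the Cre transgene and 8 were control littermates without Cre. The labelled ages were 1 week (2 Cre and 2 control mice), 3 weeks (3 and 3) and 6 weeks (3 and 3). The genotype entries of the labels were read together with the series' design text, which states a liver-specific depletion of Cdh1 and mice that were not paired. Replicate numbers were given here in accession order and only name a mouse. Per the labels' protocols, food was withdrawn for 6 hours before dissection, tissue from the middle of the left lobe was stored in RNAlater, RNA was extracted with Trizol, and Cy3-labelled cRNA was made with a Quick Amp one-colour kit.

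Per the file headers, the deposited intensity values are Agilent Feature Extraction output for 62976 features per array, and the processed signal is the spot's intensity after background subtraction and detrending within the array, with no normalization between arrays. Median spot and local background intensities, also per the file headers, are unprocessed. The authors' series matrix holds 46135 features as log2 values. Each of its columns correlated best with its own array (r from 0.9936 to 0.9982, column medians from 7.65 to 7.84). How the authors normalized and filtered those log2 values is not given in the sources used here, so it served as an alternative.

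Control spots and spots marked as outliers were left out, and spots of 1 probe were averaged. The value analysed was log2 of the processed signal minus the array's 75th percentile of it. Of 55681 probes, 26582 matched 1 gene through an accession in a RefSeq table of the mouse assembly GRCm38.p6, which was used for names alone because the arrays were designed on an older build. The other 29099 had no match and entered one alternative. The decision to test named genes was made once the annotation had been seen. Probes were kept if well above background on all arrays of at least 1 group, and each gene was represented by its probe with the highest mean, which left 17305 genes.

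Groups were compared with limma 3.58.1 in R 4.3.3: lmFit with 1 mean for each of the 6 groups, then eBayes, two-sided, with 10 residual and 2.57 prior degrees of freedom. Changes are given as log2 ± standard error, and adjusted p-values are Benjamini-Hochberg values over all genes tested, called at 0.05. Besides the contrast at each age, the fit gave their mean over ages, an F test of whether the change differed between ages, and the control livers' differences between ages. Where a gene was not well above background on any array of a group, its fold is given as "at least": the brighter group's mean against the dim group's mean of, per array, the higher of the lowest signal among probes well above background and the probe's own signal.

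A total of 32 gene lists with 454 genes, 443 of them on the array, were tested with camera at a preset correlation of 0.01, adjusted over the 32 lists. The same test with an estimated correlation, and fry, which asks whether a list's genes move one way on balance, were alternatives. The lists cover hepatocyte zones, the other liver cell types, possible neighbouring tissues, junctions, metabolism, stress and proliferation. The groups, tests, lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule names Cdh1, then the 8 genes with the largest rise and the 8 with the largest fall among called genes whose groups do not overlap (5 for differences between ages), without clone-type names. Where nothing passed, it names the 5 smallest p-values in each direction. From each list called at 1 age it names the members that passed over all genes or adjusted over the list alone, at most the 4 with the smallest p, or else the leading 2, and for the change between ages the 8 smallest p-values. List members of the mean over ages and of the control differences are not named. A few genes that the rule or an overlap would name are not reported here. For the mean over ages the condition on overlap was not applied, because no single pair of groups defines it.

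The arrays lay on 2 slides with 8 arrays each. Slide 1 held 6 Cre and 2 control arrays and slide 2 held 2 Cre and 6 control arrays. At 1 week all Cre arrays were on slide 1 and all control arrays on slide 2. Results are therefore also given with slide as a block and, at 3 and 6 weeks, within each slide. At 1 week a blocked value rests on the slide difference seen at the other ages. The shared first part of the sample titles was taken as the litter, an inference that gave 5 litters, and served as another block.

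Other alternatives were centring on the median, quantile normalization, the authors' series matrix, filters on dim probes, array weights, the mean of a gene's probes, each age fitted alone and each mouse left out. The column needed for a planned normexp correction was absent, so normexp with an offset of 50 on median signals was run instead, an alternative chosen after seeing the data. Within-slide fits and the inclusion of probes without a gene were also chosen then.

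Between 66.9% and 78.5% of probes were well above background on each array, the 75th percentile ran from 485 to 864 intensity units, and no spot was saturated. The number of arrays limits the precision. Pearson's r between mice of 1 group ran from 0.9864 to 0.9959. The fit was tested on simulated data for 17305 genes with 100 changed at each of 2 sizes. The simulated noise was independent between genes, held no slide or litter effect and was drawn 1 time per comparison. The shares below therefore do not cover the overlap of slide and genotype at 1 week and may be too high for the real arrays. For a log2 change of 1 it recovered 61% at 1 week, 75% at 3 weeks and 78% at 6 weeks, and for a log2 change of 2 it recovered 95%, 97% and 95%. Between 8 and 15 unchanged genes were called, and no recovered gene had the wrong sign. For the control differences it recovered 69% and 90% from 1 to 3 weeks, with 13 unchanged genes called, and 77% and 96% from 3 to 6 weeks, with 8. Plots were drawn with matplotlib 3.10.9.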

Results

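Liver RNA of 16 male mice was profiled at 1, 3 and 6 weeks of age to ask how the loss of Cdh1 from the liver changes gene expression as the organ matures. Cdh1 encodes E-cadherin, the adhesion protein of epithelial adherens junctions. Mice called Cre carried the deleting transgene, and control mice were littermates without it. Both were homozygous for the floxed gene. No group carried Cre with an intact Cdh1 gene, so an effect of Cre itself cannot be told apart from the loss of Cdh1. Comparisons of genotype at 1 age set 3 Cre against 3 control mice, or 2 against 2 at 1 week, and their mean over ages uses all 16. Age was the main axis of variation: the first principal component held 67% of the variance and ran from -112.3 in a control mouse at 1 week to 80.3 in a control mouse at 6 weeks.

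Cdh1 signal was lower in Cre than in control livers at every age. At 1 week it was 2.28 and 2.39 in control mice 1 and 2 and 1.27 and 1.21 in Cre mice 1 and 2 (log2 relative to the array's 75th percentile). At 3 weeks it was 0.84, 0.74 and 0.92 in control mice 1 to 3 and -1.42, -2.39 and -0.44 in Cre mice 1 to 3. At 6 weeks it was 1.13, 0.73 and 0.57 in control mice and -1.93, -2.21 and -1.65 in Cre mice. The change was -1.10 ± 0.43 at 1 week (n = 2 per group), where slide and genotype coincide. It did not pass over all genes (limma adjusted p = 1, unadjusted p = 0.025). Cdh1 fell 4.77-fold at 3 weeks (log2 change -2.25 ± 0.35, limma adjusted p = 0.022, n = 3 per group) and 6.68-fold at 6 weeks (-2.74 ± 0.35, adjusted p = 0.018). With slide as a block the changes were -0.75 (adjusted p = 1), -2.14 (0.036) and -2.62 (0.022). With litter as a block they were -1.10 (1), -2.28 (0.037) and -2.74 ± 0.40 (0.068), so the 6-week call was lost. Within slides 1 and 2 they were -2.75 and -1.27 at 3 weeks and -3.20 and -2.30 at 6 weeks, from 2 Cre against 1 control mouse on slide 1 and 1 against 2 on slide 2. Whether the Cdh1 probe lies in the deleted part of the gene is not given in the sources used here, and the signal comes from all cells of the tissue piece, not hepatocytes alone.

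**Figure D1:**
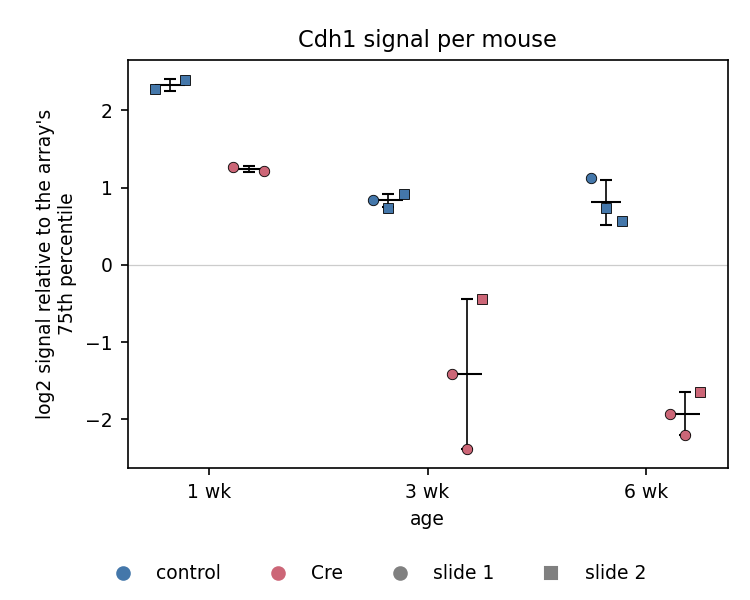
Cdh1 signal of each mouse (points, log2 relative to the array's 75th percentile) by age, with the group mean and SD as bars and the slide as the point's shape. Control mice at 3 and 6 weeks lie between 0.57 and 1.13, and Cre mice of these ages between -2.39 and -0.44.

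At 1 week no gene passed. The genes with the smallest p-values included Kcnab1, a potassium channel subunit (log2 change 1.07 ± 0.20), Tgm3, a transglutaminase (0.93 ± 0.18), Abcc8 (0.62 ± 0.15), Mroh1 (0.59 ± 0.14) and Cxcl15, a chemokine not well above background in control livers (at least 1.5-fold), on the higher side. On the lower side were Serpina3k, a serine protease inhibitor (-1.09 ± 0.22), Tgm7 (-1.17 ± 0.25), Tspoap1 (-0.58 ± 0.14), and Prss43 and the serotonin receptor Htr2c, at least 2.51-fold and 2.18-fold lower and not well above background in Cre livers. All 10 had a limma adjusted p of 1. The interferon response list was lower in Cre livers, with a median log2 change of -0.71 over 16 members, all of them lower (camera adjusted p = 4.8e-10). With an estimated correlation its p was 0.046 (adjusted p = 0.91), and 0 members passed adjusted over the list alone or over all genes. Isg15 (-0.94 ± 0.30) and Ifit3 (-0.95 ± 0.35), both induced by interferon, led the list.

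limma called 0 genes at 1 week and found 493 at an unadjusted p under 0.05, against 0 and 484 with slide as a block and 0 and 664 with litter as a block. All Cre arrays of this age lay on slide 1 and all control arrays on slide 2, so slide and genotype can be separated only through the other ages. The interferon list's median was -0.75 with slide as a block. The 1-week list call moved with single mice: 0 lists passed without control mouse 1 at 1 week.

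At 3 weeks 289 genes changed, 79 up and 210 down. Genes that rose included Dmbt1, a secreted scavenger receptor protein of epithelia (log2 change 6.66 ± 1.18, adjusted p = 0.027), well above background in 1 of 3 control and 3 of 3 Cre livers. Fos, an immediate early transcription factor, rose 3.87-fold (1.95 ± 0.33, adjusted p = 0.023). Bex1 rose 4.66-fold, the tetraspanin Tspan8 3.67-fold and the signalling ligand Wnt10a 3.62-fold, the last well above background in 1 of 3 control livers. Col6a5, a collagen VI chain, rose at least 2.35-fold, Kif5c, a kinesin heavy chain, at least 1.84-fold and Tmeff1 at least 1.25-fold, none of them well above background in control livers. Tmeff1 was well above background in 2 of 3 Cre livers. Genes that fell included the serpin pseudogene Serpina4-ps1 (-6.30 ± 0.97, adjusted p = 0.022) and the sulfotransferase Sult3a1, which was at least 9.67-fold lower (adjusted p = 0.0066) and not well above background in Cre livers. Acsm2, an acyl-CoA synthetase well above background in 1 of 3 Cre livers, fell 6.27-fold, Serpina9 5.67-fold and Nudt7, a peroxisomal coenzyme A diphosphatase, 3.91-fold. Olfr1474, an olfactory receptor gene, fell 3.38-fold and Atp8b5, a phospholipid flippase, 3.35-fold, although another Atp8b5 probe changed by -0.02. Adjusted p-values of the 16 named genes were from 0.0066 to 0.048, and the serpins and sulfotransferases have close relatives that a probe can also bind.

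Cell cycle genes were lower together at 3 weeks: the median log2 change was -0.86 over 18 members, all of them lower (camera adjusted p = 4.1e-09). With an estimated correlation the p was 0.02 (adjusted p = 0.16). Over all genes 4 members fell: Ccna2 (-1.08 ± 0.20) and Ccnb2 (-1.05 ± 0.21), the cyclins of S phase and mitosis, Birc5 (-1.23 ± 0.25) and Cdc20 (-1.09 ± 0.22), and 14 fell adjusted over the list alone. The list's median was -0.58 within slide 1 and -1.01 within slide 2. Male-biased liver genes had a median of -0.95 over 11 members (camera adjusted p = 0.00042, p = 0.085 with an estimated correlation). No member passed over all genes and 6 fell adjusted over the list alone, among them Hsd3b5 (-4.50 ± 1.11), Mup20 (-2.69 ± 0.71), Egfr (-1.27 ± 0.31) and Igf1 (-0.50 ± 0.14). Within slides the medians were -0.92 and -1.13.

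Immediate early and handling stress genes were higher, with a median of 0.61 over 13 members (camera adjusted p = 0.00013, p = 0.013 and adjusted p = 0.14 with an estimated correlation). Klf6 (0.91 ± 0.15) and Fos rose over all genes, and 4 members rose adjusted over the list alone, with Ier3 (0.97 ± 0.24) and Atf3 (1.58 ± 0.43) added. The medians within slides were 0.80 and 0.37. These genes respond within minutes to tissue handling, and their values stand beside every other 3-week list. The Kupffer cell and macrophage list had a median of 0.57 with all 14 members higher (adjusted p = 3.9e-06, p = 0.09 with an estimated correlation). None passed over all genes and 6 rose adjusted over the list alone, including the complement genes C1qa (0.73 ± 0.17) and C1qb (0.57 ± 0.17), Clec4f (0.51 ± 0.14) and Cd14 (1.07 ± 0.31). Endothelial genes had a median of 0.38 over 11 members (adjusted p = 0.00016, p = 0.0023 and adjusted p = 0.072 with an estimated correlation), with 0 rising over all genes and 6 adjusted over the list alone, such as Eng (0.40 ± 0.10), Pecam1 (0.38 ± 0.09), Stab1 (0.49 ± 0.13) and Stab2 (0.30 ± 0.08). Epithelial-mesenchymal transition genes had a median of 0.49 over 12 members (adjusted p = 0.00016, p = 0.012 and adjusted p = 0.14 with an estimated correlation). Of these the matrix metalloprotease Mmp14 (0.87 ± 0.20) rose over all genes and 4 rose adjusted over the list alone, the others being Foxc2 (0.93 ± 0.25), Zeb1 (0.26 ± 0.09) and Vim (0.68 ± 0.24).

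Cholangiocyte and progenitor genes had a median of 0.43 at 3 weeks with 16 of 17 members higher (adjusted p = 0.00016, p = 0.046 with an estimated correlation), and Dmbt1 was the member that passed, over all genes and adjusted over the list alone. Targets of YAP had a median of 0.41 (adjusted p = 0.0013, p = 0.029 with an estimated correlation), with 0 passing over all genes and 2, Crim1 (0.43 ± 0.12) and Axl (0.69 ± 0.20), adjusted over the list alone. Stellate cell and fibrosis genes had a median of 0.46 (adjusted p = 0.0013, p = 0.18 with an estimated correlation), led by Tgfb1 (0.46 ± 0.16) and Timp1 (1.72 ± 0.60), with 0 members passing either way. The cytokine and chemokine median was 0.53 (adjusted p = 0.0019, p = 0.14 with an estimated correlation), and Icam1 (0.88 ± 0.24) rose adjusted over the list alone but not over all genes. Interferon response genes had a median of 0.41 (adjusted p = 0.0059, p = 0.33 with an estimated correlation, adjusted p = 0.16 with litter as a block), and Oasl2 (0.82 ± 0.33) and Irf7 (0.76 ± 0.33) did not pass.

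Among metabolic lists at 3 weeks, cholesterol synthesis had a median of -0.43 (adjusted p = 0.0026, p = 0.31 with an estimated correlation), and Sc5d (-0.67 ± 0.17) and Idi1 (-1.12 ± 0.33) fell adjusted over the list alone, with 0 over all genes. Lipogenesis had a median of -0.44 (adjusted p = 0.0084, p = 0.13 with an estimated correlation), and the fatty acid elongase Elovl6 (-1.42 ± 0.31) fell over all genes and adjusted over the list alone. Fasting and fatty acid oxidation genes had a median of 0.53 (adjusted p = 0.0059, p = 0.32 with an estimated correlation) but -0.06 within slide 1 and 1.02 within slide 2, and Pdk4 (1.17 ± 0.33) did not pass. Pericentral hepatocyte and beta-catenin target genes had a median of -0.30 (adjusted p = 0.038, p = 0.35 with an estimated correlation), led by Lect2 (-0.74 ± 0.23) and Sp5 (-0.79 ± 0.32), which did not pass. Medians within slides 1 and 2 were -0.28 and -0.63 for cholesterol synthesis, -0.53 and -0.45 for lipogenesis and -0.13 and -0.44 for pericentral genes. Of the 15 lists called at 3 weeks, 0 passed adjustment with an estimated correlation, 6 had an unadjusted p under 0.05 there, and fry called 7. fry also called the endoplasmic reticulum stress list, which camera did not.

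Of the 289 genes 71 changed at least 2-fold. With slide as a block 155 genes were called, 38 up and 117 down, 137 of them shared with the 289, and with litter as a block 376, of which 181 were shared. Among the named genes Bex1, Tspan8 and Olfr1474 were not called with slide as a block (adjusted p = 0.053, 0.062 and 0.067), nor Tspan8, Olfr1474 and Kif5c with litter as a block (0.084, 0.076 and 0.05). The 3-week count moved with single mice, those of other ages included. It was 7 without Cre mouse 3 and 571 without Cre mouse 1 of that age, and 4 when the age was fitted alone. Of the 93 called genes measured by several probes, 82 had the same sign on all of them.

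At 6 weeks 73 genes changed, 69 up and 4 down. Slpi, a secreted protease inhibitor, rose 9.89-fold (log2 change 3.31 ± 0.58, adjusted p = 0.036). Foxj1, a transcription factor of motile cilia, rose 5.87-fold (adjusted p = 0.043), well above background in 2 of 3 control livers, and Tspan8 rose 5.75-fold (adjusted p = 0.028). Another 5 genes were not well above background in control livers: Dmbt1 rose at least 25.1-fold, Gipc2 at least 6.98-fold, Col6a5 at least 3.39-fold, Aoc1, a diamine oxidase, at least 3-fold and the homeobox gene Meox1 at least 2.37-fold (adjusted p from 0.022 to 0.042). Aoc1 was well above background in 2 of 3 Cre livers. Besides Cdh1, the kinase gene Alpk3 (-0.70 ± 0.13, adjusted p = 0.042), Adam18 (-0.69 ± 0.09, adjusted p = 0.018) and Gm128 (-0.74, adjusted p = 0.028) fell, the last named after its values were seen.

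**Figure D2:**
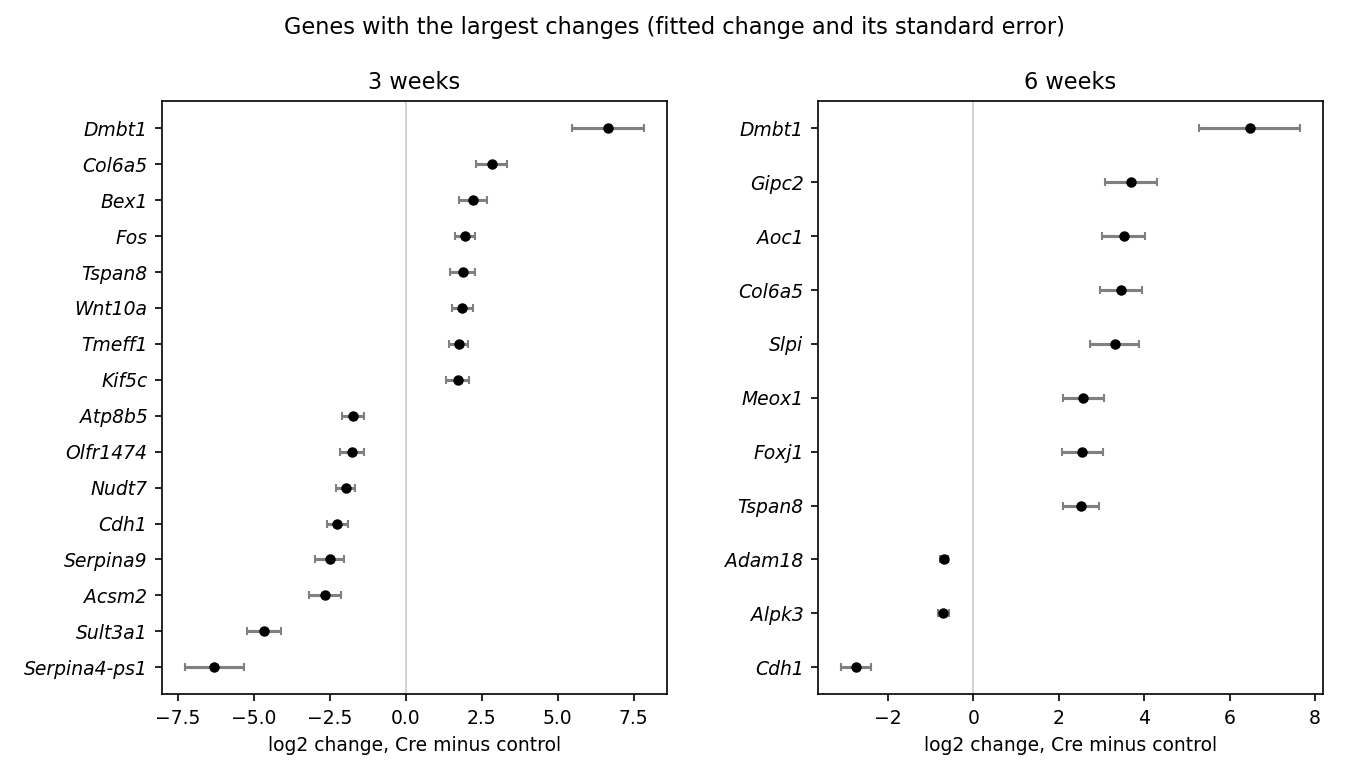
Fitted log2 change between Cre and control livers of the genes named by the fixed rule at 3 weeks (left) and 6 weeks (right), with bars of 1 standard error (n = 3 per group). Dmbt1 lies highest at both ages, at 6.66 and 6.47, values that depend on signals near background in control livers.

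Cholangiocyte and progenitor genes, markers of bile duct cells, were higher together at 6 weeks, with a median log2 change of 0.65 and 16 of 17 members higher (camera adjusted p = 6.6e-08). With an estimated correlation the p was 0.0083 (adjusted p = 0.27), and the fry adjusted p was 0.017. Over all genes 3 members rose and adjusted over the list alone 10 rose, including Dmbt1, the duct keratins Krt19 (1.87 ± 0.35) and Krt7 (1.98 ± 0.38), and Cd24a (1.68 ± 0.35). The median was 0.64 within slide 1 and 1.02 within slide 2. Stellate cell and fibrosis genes had a median of 0.65 with 14 of 15 members higher (adjusted p = 2.8e-07, p = 0.044 and adjusted p = 0.46 with an estimated correlation). None passed over all genes; adjusted over the list alone 11 rose and 1 fell, with Timp1 (2.65 ± 0.60), an inhibitor of matrix proteases, and the collagens Col1a1 (2.16 ± 0.50), Col3a1 (1.64 ± 0.42) and Col1a2 (1.39 ± 0.36) leading and Tagln (-0.47 ± 0.15), named after its value was seen, falling. The medians within slides were 0.56 and 0.74. The endothelial list, markers of another cell type, had a median of 0.07 (adjusted p = 0.56), and the Kupffer cell list 0.19 (adjusted p = 0.071, or 0.025 with slide as a block).

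Epithelial-mesenchymal transition genes had a median of 0.42 at 6 weeks (adjusted p = 0.0068, p = 0.033 and adjusted p = 0.46 with an estimated correlation), and Mmp2 (1.41 ± 0.28), Vim (0.87 ± 0.24) and Mmp9 (at least 1.25-fold, not well above background in control livers) rose adjusted over the list alone, with 0 over all genes. The other 5 lists called at 6 weeks had 0 members passing over all genes or adjusted over the list alone. Cytokine and chemokine genes had a median of 0.43 (adjusted p = 0.012, p = 0.18 with an estimated correlation), led by Ccl2 (1.90 ± 0.67) and Ccl4 (0.62 ± 0.22, well above background in 2 of 3 control livers). Pericentral genes had a median of -0.26 (adjusted p = 0.0068, p = 0.20 with an estimated correlation), led by Notum (-0.42 ± 0.12) and Cyp2e1 (-0.24 ± 0.11). General hepatocyte genes had a median of -0.15 (adjusted p = 0.013, p = 0.19 with an estimated correlation), with Alb at -0.16 ± 0.09 and Ttr at -0.15 ± 0.09, and Alb was 0.00 under quantile normalization. Cell cycle genes had a median of 0.38 (adjusted p = 0.021, p = 0.26 with an estimated correlation), led by Top2a (0.92 ± 0.25) and by Bub1, which was not well above background in control livers and is given no fold. Cholesterol synthesis genes had a median of 0.40 (adjusted p = 0.019, p = 0.38 with an estimated correlation), with Sqle at 0.74 ± 0.35, but with slide as a block the adjusted p was 0.076. Medians within slides 1 and 2 were -0.07 and -0.51 for pericentral, 0.00 and -0.16 for general hepatocyte, -0.04 and 0.32 for cholesterol synthesis, 0.24 and 0.64 for cell cycle, 0.67 and 0.49 for cytokine and chemokine and 0.48 and 0.30 for epithelial-mesenchymal transition genes. Of the 8 lists called, 0 passed adjustment with an estimated correlation and fry called 1.

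With slide as a block 43 genes were called at 6 weeks, 39 up and 4 down, 40 of them shared with the 73, and Slpi, Meox1 and Foxj1 were not called (adjusted p = 0.066, 0.076 and 0.076). With litter as a block limma called 0 genes (2185 at an unadjusted p under 0.05, 2036 without the block). Litters are balanced at this age, so the changes stay the same by design and the block alters only their standard errors (Cdh1 -2.74 ± 0.40 against ± 0.35) and the residual degrees of freedom, 7 against 10. The 6-week count was 996 without Cre mouse 2, 0 without Cre mouse 3 (limma, 1279 at an unadjusted p under 0.05) and 0 without control mouse 1 (1903). Cre mouse 2 lay at 70.7 on the first principal component, beside control mice at 71.8 to 80.3 and the other Cre mice at 48.2 and 48.9, while its Cdh1 signal was low. Of 13 called genes with several probes 10 had the same sign on all of them.

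**Figure D3:**
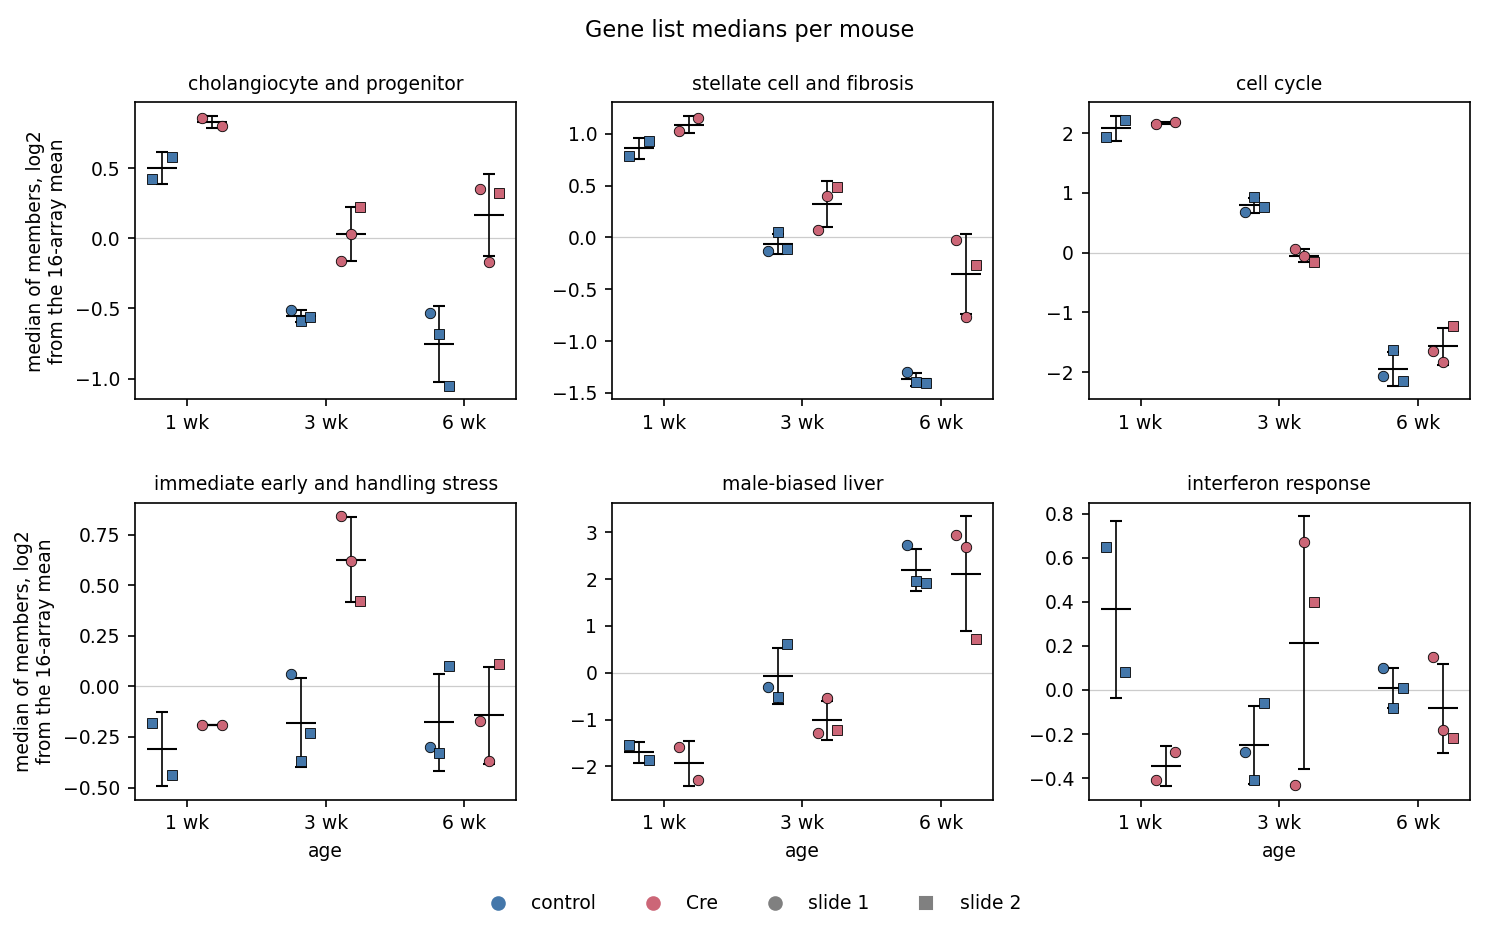
Median of 6 gene lists in each mouse (points, log2 distance from the mean of all 16 arrays) by age, with the group mean and SD as bars and the slide as the point's shape. Cholangiocyte medians at 6 weeks lie from -0.17 to 0.35 in Cre mice and from -1.05 to -0.53 in control mice, and cell cycle medians at 3 weeks from -0.16 to 0.07 in Cre and from 0.69 to 0.93 in control mice.

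Comparing ages, 11 genes rose at both 3 and 6 weeks, against 0.31 expected if the calls were independent (Fisher's exact test, p = 1.28e-14). Both changes share 1 residual variance per gene, so the calls are not independent and nothing is concluded from this p-value. Among the 11 genes were Adamtsl2, Col6a5, Dmbt1, Eid2, Gpx3, Lmo1, Mmp7, Tff2, Tmeff1 and Tspan8, named because they overlap and after their values were seen. At 3 weeks Mmp7, Tff2 and Tspan8 were not called with slide as a block (limma adjusted p = 0.053, 0.056 and 0.062). With litter as a block these 3 were not called either (0.059, 0.059 and 0.084). The ages share no arrays, but Cre arrays lie mostly on slide 1 at both, and with litter as a block limma called 0 genes at 6 weeks (2185 at an unadjusted p under 0.05). Cdh1 was the gene that fell at both ages. Of the 73 genes called at 6 weeks, 71 had the same sign at 3 weeks, and of the 289 called at 3 weeks, 210 had the same sign at 6 weeks. The share with the same sign over all genes was not counted. Of the 69 genes that rose at 6 weeks, 67 were higher at 3 weeks and 38 at 1 week. Averaged over ages limma called 5 genes, with 2574 at an unadjusted p under 0.05. Cdh1 (-2.03 ± 0.22, adjusted p = 0.0096) fell. The trefoil peptide Tff2 (1.53 ± 0.22), the epithelial protease Mmp7 (1.40 ± 0.20), Eid2 (0.80 ± 0.10) and Col6a5 rose. Col6a5 was not well above background in control livers at 3 and 6 weeks. The limma adjusted p-values of the 4 that rose ran from 0.033 to 0.046. They pass only because Cdh1, the deleted gene, is ranked ahead of them, and without it none would pass. With slide or with litter as a block limma called 0 genes on average (2367 and 2755 at an unadjusted p under 0.05), where Cdh1 was -1.84 ± 0.25 (adjusted p = 0.13) and -2.04 ± 0.26 (0.11). Averaged over ages 12 lists were called, 8 up and 4 down, led by the cholangiocyte list (median 0.55, adjusted p = 4.9e-08, p = 0.008 and adjusted p = 0.14 with an estimated correlation), and 0 passed adjustment with an estimated correlation.

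The test of whether the change differed between ages called 0 genes (limma F test, smallest adjusted p = 0.139, 1671 genes at an unadjusted p under 0.05). The smallest p-values belonged to Kif2c, a mitotic kinesin, with changes of 0.08, -1.01 and 1.23 at 1, 3 and 6 weeks, Gnat2 (0.18, -1.45 and 0.20), Aldh1a7 (0.46, -1.60 and 0.29) and Cdca2 (0.22, -1.02 and 0.27). Next were 1700057G04Rik, at least 2.52-fold lower at 3 weeks, where it was not well above background in Cre livers, and Duxbl2 and Parpbp, at least 1.45-fold and 1.55-fold higher at 6 weeks, where they were not well above background in control livers. In the direct contrast of the 6-week with the 3-week change, Kif2c passed (2.25, adjusted p = 0.041), but with litter as a block limma called 0 genes there (2044 at an unadjusted p under 0.05). It was the gene called in opposite directions at the 2 ages, but at 6 weeks it was not well above background in any liver, so its 6-week value and this contrast rest on signals near background.

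In control livers 8434 genes differed between 1 week (2 mice) and 3 weeks (3 mice), 4512 up and 3922 down. Afp, the fetal serum protein alpha-fetoprotein, fell by 9.67 on the log2 scale (SE 0.35, limma adjusted p = 1.7e-09). The largest rises were of the major urinary protein genes Mup18, Mup17, Mup3 and Mup19 (log2 changes from 10.60 to 12.15) and Mup6 (at least 2240-fold, not well above background in control livers at 1 week), and the largest falls of the stefin-type genes Stfa1, Cstdc5, Cstdc4 and Stfa2l1 (-12.04 to -10.32), families of near-identical copies whose single members are uncertain. Of 19 lists that camera called, 0 passed adjustment with an estimated correlation (smallest adjusted p = 0.056). Their medians included neutrophil (-6.53), fetal and neonatal liver (-3.38), erythroid (-3.19), periportal hepatocyte (1.83) and xenobiotic metabolism genes (1.48), with camera adjusted p from 4.4e-06 to 0.0018 and p of 0.035, 0.0035, 0.055, 0.13 and 0.027 with an estimated correlation. Cdh1 fell by 1.5 (adjusted p = 0.0069, or -1.47 ± 0.59 and 0.078 with litter as a block). From 3 to 6 weeks (3 control mice each) 3866 genes differed, 1596 up and 2270 down. By the inferred litters, no litter held mice of both these ages. A litter block therefore cannot separate litter from age here, and no blocked result is given. Cyp4a12b (6.75 ± 0.38), Cyp4a12a (6.59 ± 0.40), Nat8f5 (6.70 ± 0.68) and Olfr677 (5.0 ± 0.55, well above background in 1 of 3 livers at 3 weeks) rose, and Sult2a2 (-11.43 ± 0.59, well above background in 2 of 3 livers at 6 weeks) fell. Sult2a1, Sult2a4, Sult2a6 and Hsd3b1 fell at least 4150-fold, 1870-fold, 2120-fold and 240-fold and were not well above background at 6 weeks. The Sult2a and Cyp4a12 members are again uncertain. The probe used for Pax2 rose by 7.71 while another changed by 0.15. Male-biased genes had a median of 2.86 (8 of 11 members rose over all genes) and cell cycle genes one of -2.66 (16 of 18 fell), with p of 0.029 and 0.0042 with an estimated correlation, where 0 of the 5 lists camera called passed adjustment (smallest adjusted p = 0.13). Cdh1 changed by -0.02, which did not pass. By the inferred litters, mice of 1 and 3 weeks came partly from different litters, so age and litter overlap. Mice of 3 and 6 weeks came wholly from different litters, so age and litter cannot be told apart there.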

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

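All tests of explanations in this part were chosen only after the result was seen, except the counts of other splits of the mice, which were planned. The tests of a lag on the cell cycle list alone, and of both lists with slide or litter as a term, were added after a joint test with the male-biased list had left a shift in age open, and all are given.

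Several lists changed differently at 3 weeks than at 1 week by camera on the difference itself. For each list the median over members of the 3-week minus the 1-week log2 change was taken. This median difference was 1.06 for interferon response, 0.81 for cytokines and chemokines and 0.77 for Kupffer cells and macrophages. It was 0.54 for epithelial-mesenchymal transition, 0.54 for fasting and fatty acid oxidation and 0.52 for cholangiocytes and progenitors. It was 0.45 for immediate early and handling stress, 0.43 for stellate cells and fibrosis, 0.35 for YAP targets and 0.29 for endothelial genes. It was -0.96 for male-biased liver, -0.91 for cell cycle, -0.66 for cholesterol synthesis, -0.50 for lipogenesis and -0.39 for pericentral hepatocyte genes. Adjusted p-values ran from 2.5e-08 to 0.031, and 0 of these lists passed adjustment with an estimated correlation (smallest adjusted p = 0.26). At 1 week slide and genotype coincide. With slide as a block 5 of these lists were not called: cholangiocytes and progenitors (0.34, adjusted p = 0.063), stellate cells and fibrosis (0.39, 0.064), lipogenesis (-0.46, 0.063), pericentral hepatocyte (-0.32, 0.05) and fasting and fatty acid oxidation genes (0.37, 0.05). The male-biased difference was -0.86 (0.021), but its median per mouse changed by -0.95 ± 0.72 at 1 week and -1.18 ± 0.52 at 3 weeks in that fit, against -0.23 ± 0.69 and -0.94 ± 0.57 without the block, so the size of this difference depends on slide and on how the list is summarised. With litter as a block cholangiocytes (0.14), stellate cells (0.14) and YAP targets (0.062) were not called.

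Between 6 and 3 weeks the change in Cre livers differed for the mitotic kinesin gene Kif2c (2.25 on the log2 scale, limma adjusted p = 0.041), which was not well above background in any liver at 6 weeks. With litter as a block limma called 0 genes for this difference (2044 at an unadjusted p under 0.05). By the same camera test the median over members of this difference was 1.19 for cell cycle and 0.86 for cholesterol synthesis genes. It was 0.70 for lipogenesis and 0.46 for male-biased liver genes. It was -0.64 for fasting and fatty acid oxidation, -0.49 for interferon response, -0.49 for immediate early and handling stress, -0.31 for Kupffer cells and macrophages and -0.27 for endothelial genes. Adjusted p-values ran from 1.5e-14 to 0.045, and 0 passed adjustment with an estimated correlation (smallest adjusted p = 0.092). With litter as a block interferon response was not called (adjusted p = 0.090).

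Among 20585 probes without a named gene, which the comparisons above left out, limma called 3 at 1 week (3 higher in Cre livers), 24 at 3 weeks (9 higher, 15 lower) and 6 at 6 weeks (5 higher, 1 lower).

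Bile duct and stellate cell genes were higher in Cre livers at 6 weeks. With slide as a term the change of the cholangiocyte list's median per mouse was 0.93 ± 0.18 and that of the stellate list 1.05 ± 0.18, which argues against slide as the whole cause. By the inferred litters, each held as many Cre as control mice at this age, so a difference between litters cancels out of the change. With litter as a term the changes of 0.92 ± 0.19 and 1.02 ± 0.19 are the same by design and test nothing further. If the titles do not mark litters, litter stays open. A smaller share of hepatocytes would raise markers of the other cell types alike, but the cholangiocyte list rose above the endothelial list by 0.82 ± 0.15. A larger share of bile duct and stellate cells, or higher expression within cells, may account for it and was not separated. At 3 weeks the cholangiocyte and endothelial medians per mouse both rose, by 0.58 ± 0.16 and 0.32 ± 0.09. A smaller share of hepatocytes at that age was not tested.

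Cell cycle genes were lower in Cre livers at 3 weeks. The change of the list's median was -0.79 ± 0.17 with slide as a term and -0.81 ± 0.21 with litter as a term, so neither is likely to be the whole cause. Cell cycle genes fall with age in control livers, so a lag of Cre livers along the postnatal course would make them higher, and the change of -0.84 ± 0.17 argues against it for this list. Male-biased genes rise with age, so a shift in age in either direction would move both lists apart; their change was -1.18 ± 0.52 with slide and -1.18 ± 0.43 with litter as a term, which with the cell cycle values argues against a shift, but -0.94 ± 0.57 with neither, so that outcome depends on the block and a shift stays open for these genes. An effect of the genotype on proliferation stays a hypothesis.

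The interferon list was lower in Cre livers at 1 week, where slide and genotype coincide. The slide difference for the interferon list estimated from 3 and 6 weeks was 0 ± 0.20. With slide as a term the 1-week change was -0.71 ± 0.39, within 2 standard errors of 0, so slide cannot be told apart from genotype here. Without it the change of the list's median was -0.71 ± 0.31. That is past the 2 standard errors set as a bound for variation between mice, but the list was picked as the most extreme of 32, for which this bound is too lax, so variation between mice may still account for it.

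Other splits of the same mice were counted. The 10 splits of 3 against 3 mice are too few for a share under 0.05. At 3 weeks 1 of the 10 splits, the real one, gave 289 genes and the highest other gave 2. At 6 weeks it was 1 of 10, with 73 genes and 5 in the highest other. Between control livers at 6 and 3 weeks it was 1 of 10, with 3866 genes and 1. For lists at 3 weeks it was 1 of 10, with 15 lists and 10 in the highest other. For lists at 6 weeks 5 of the 10 splits gave at least the real 8, and the split that follows the slides gave the highest other, 11; with slide as a block 9 lists were called. For the mean over ages, 1 of 100 splits gave as many as the real 5 genes (highest other 3), a share under 0.05. These splits ignore slide and litter, and the 5 include Cdh1, which the design deletes. The 4 that rose have unadjusted limma p-values from 3.8e-06 to 1.3e-05 and pass only with Cdh1 ranked ahead of them. Without Cdh1 among the genes tested none of the 4 would pass, so this share says nothing about them. With slide or with litter as a block limma called 0 genes on average (2367 and 2755 at an unadjusted p under 0.05), but the changes moved little. Cdh1 was at -1.84 ± 0.25 and -2.04 ± 0.26, against -2.03 ± 0.22. With slide, Tff2, Mmp7 and Eid2 were at 1.62, 1.37 and 0.75, and with litter at 1.49, 1.41 and 0.81, against 1.53, 1.40 and 0.80. For these genes the lost calls do not point to slide or litter as the cause. For lists on average 13 of 100 splits gave at least the real 12 (highest other 18), so a random grouping is not excluded for that count. The list counts at a preset correlation are therefore a weak guide to how many lists moved.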

How the results depend on the processing

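Within-slide fits, normexp on median signals and the inclusion of probes without a gene were chosen after seeing the data; the planned normexp on mean signals was not run because its column was absent. Replicate numbers only name mice, and the design text calls the mice not paired, so litter, read from the titles, was the block fitted. Within a slide 1 group has a single mouse (2 Cre against 1 control on slide 1, 1 against 2 on slide 2), so a call lost there does not speak against the result. Where not stated otherwise, the cause was not tested.

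Against 0 genes at 1 week, there were 5 without a filter on dim probes and 3 with probes without a gene. Against 289 genes at 3 weeks, there were 71 at a minimum of 2-fold, 152 after quantile normalization, 146 without a filter, 500 with probes well above background on all arrays, 155 with slide as a block, 4 with each age fitted alone (fewer samples), 947 with array weights, 80 with probes without a gene (more features tested), 2 within slide 1 and 1 within slide 2. Against 73 at 6 weeks, these settings gave 48 after quantile normalization, 22 on the authors' series matrix, 14 with normexp, 45 without a filter, 45 with probes well above background on all arrays, 43 with slide and 0 with litter as a block, 0 with each age fitted alone (limma, 1630 at an unadjusted p under 0.05), 295 with array weights, 33 with probes without a gene, 0 within slide 1 (669) and 9 within slide 2. Against 5 on average over ages there were 8 on the series matrix (50% higher against 80%), 1 with normexp (0% higher), 8 with probes well above background on all arrays, 0 with slide or litter as a block and 540 with array weights. Against 0 genes whose change differed between ages there were 1 without a filter, 1 with slide as a block and 2 with probes without a gene. Control differences gave 13701 (1 to 3 weeks) and 6639 (3 to 6 weeks) with probes without a gene, and 457 for the latter with litter as a block.

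Cdh1 kept its direction in all of them. It no longer passed at 3 weeks with the age fitted alone (-2.25, adjusted p = 0.14) and within slides 1 (-2.75, 0.39) and 2 (-1.27, 0.18), nor at 6 weeks with litter as a block (-2.74, 0.068), the age fitted alone (-2.74, 0.15) and within slide 1 (-3.20, 0.33). Lists called at 1 week were 4 on the series matrix and 3 with normexp, against 1. With an estimated correlation 0 lists passed at 1, 3 and 6 weeks and on average, and fry called 0, 8, 1 and 5. Within slide 1 at 3 weeks 9 lists were called, against 15. Alb at 6 weeks went to 0.00 after quantile normalization and 0.00 with normexp, Cdh1 in controls from 3 to 6 weeks to 0.01 with normexp, and the cholesterol synthesis list at 6 weeks to -0.04 within slide 1. For other single genes 792 values were the same in direction and call, 91 lost and 20 gained their call. These counts include the litter block from 3 to 6 weeks in controls, which cannot separate litter from age. For single lists 248 were the same and 85 lost their call. The median of all genes moved above 0.1 only from 1 to 3 weeks in controls, up to 0.138.

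Leaving out 1 mouse at a time gave 0 to 1 genes at 1 week (1 without control mouse 2), 7 to 571 at 3 weeks, 0 to 996 at 6 weeks, 0 to 537 on average, 0 to 74 whose change differed between ages, 6189 to 8810 between 1 and 3 weeks and 2617 to 4284 between 3 and 6 weeks in controls. Cdh1 ran from -1.15 to -1.04, -2.74 to -1.77 and -2.88 to -2.58 at the 3 ages, and lists from 0 to 5, 11 to 16, 6 to 10 and 10 to 15 on average. The 3-week count was 59 without either 1-week Cre mouse, 187 without either 1-week control, 65, 48 and 9 without 3-week controls 1 to 3, 571, 499 and 7 without 3-week Cre mice 1 to 3, 133 and 141 without 6-week controls 1 and 2, and 551 without 6-week Cre mouse 2. The 6-week count was 29 without either 1-week Cre mouse, 46, 46 and 42 without 3-week controls, 42 and 39 without 3-week Cre mice 2 and 3, 0, 30 and 3 without 6-week controls 1 to 3, and 2, 996 and 0 without 6-week Cre mice 1 to 3. The average count was 2 without either 1-week Cre mouse, 3 and 0 without 1-week controls, 3, 2 and 1 without 3-week controls, 17 and 1 without 3-week Cre mice 1 and 3, 3 and 2 without 6-week controls 1 and 3, and 537 and 1 without 6-week Cre mice 2 and 3. Genes differing between ages were 74 without 6-week Cre mouse 2, 3 without 1-week control 2, 1 without 3-week control 2 and 3 without 6-week control 2. The 1-week list count was 5 and 2 without Cre mice 1 and 2, 0 and 5 without controls 1 and 2 of that age, and 2 without 3-week Cre mouse 2, 6-week controls 1 or 3 or 6-week Cre mouse 2. Cdh1 lost its call at 3 weeks without control 3 (adjusted p = 0.087) and at 6 weeks without controls 1 (0.051) or 3 (0.06) or Cre mice 1 (0.065) or 3 (0.073). A lone mouse of a group is assumed to vary like the other groups.

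Signal over background limits the folds of genes that were dim in 1 group: of the 73 calls at 6 weeks 21 were dim in controls alone and 1 in both groups, and at 3 weeks 6 were dim in controls alone, 2 in Cre livers alone and 4 in both.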

Other observations

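The comparison of all genes with the postnatal course below was planned before its result was seen; the genes and lists named first were chosen after their values were seen.

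At 3 weeks camera did not call the endoplasmic reticulum stress list (median -0.08 over 13 members, adjusted p = 0.10). Pdia4 (-0.66 ± 0.15, limma adjusted p = 0.048) fell over all genes, and adjusted over the list alone 5 members fell, among them Sdf2l1 (-1.38 ± 0.33), Hsp90b1 (-0.47 ± 0.12), Hspa5 (-0.49 ± 0.13) and the transcription factor Xbp1 (-0.49 ± 0.19), while Ddit3 (0.56 ± 0.19) rose. Of the acute phase genes (median 0.08, adjusted p = 0.50), Orm1 (-1.71 ± 0.40) and Orm2 (-1.53 ± 0.42), near-identical copies, fell and Lbp (0.65 ± 0.19) rose adjusted over the list alone, with 0 over all genes. The elastase gene Cela1 (-1.52 ± 0.25, adjusted p = 0.023) fell, while the exocrine pancreas list that holds it had a median of -0.18 (adjusted p = 0.26). In the adherens junction list (median -0.03 at 3 weeks and 0.05 at 6 weeks, adjusted p = 0.63 and 0.70), Cdh2, the N-cadherin gene, fell (-0.29 ± 0.09) adjusted over the list alone beside Cdh1. In the glutathione list (median 0.06, adjusted p = 0.99) the catalase gene Cat (-0.56 ± 0.15) fell adjusted over the list alone.

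At 6 weeks the YAP target Ankrd1 (1.62 ± 0.46, well above background in 1 of 3 control livers) and the lymphocyte list's Ltb (1.08 ± 0.25) rose adjusted over their lists alone, while their lists had medians of 0.19 and 0.10 (adjusted p = 0.057 and 0.92). The neutrophil list had a median of 0.45 at 3 weeks and 0.85 at 6 weeks (adjusted p = 0.23 and 0.13), with S100a9 at 1.59 ± 0.69 and S100a8 at 1.51 ± 0.66 at 6 weeks, which did not pass. Lists called in no comparison of Cre with control livers at one age had these medians at 3 and 6 weeks: tight and gap junction 0.08 and 0.16, periportal hepatocyte 0.00 and -0.09, erythroid -0.32 and -0.18, skeletal muscle 0.38 and 0.07, adipose tissue 0.11 and -0.03, bile acid synthesis and transport 0.00 and -0.09, xenobiotic metabolism -0.12 and 0.05, fetal and neonatal liver 0.26 and 0.25, and circadian clock -0.06 and 0.04. The male-biased list had a median of -0.38 at 6 weeks (adjusted p = 0.11, or 0.028 with slide as a block).

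A hypothesis is that Cre livers lag the postnatal course at 3 weeks. Across 17305 genes, which are not independent replicates, the 3-week change correlated with the control livers' difference between 6 weeks and 1 week at r = -0.374 (Spearman's rho -0.353), from -0.376 to -0.330 with each 3-week mouse left out, and the sets share no arrays. The 1799 genes at least 2-fold higher at 6 weeks had a median 3-week change of -0.15, and the 2943 at least 2-fold lower one of 0.25. The sign is that of a lag, but among the other splits of the 6 mice at 3 weeks the largest size of r was 0.304, and 10 splits are too few for a share under 0.05. Mice of 1 age may differ in maturity for other reasons, and cell cycle genes, at -0.84 ± 0.17, go against a lag.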
